A study of Caenorhabditis elegans with 6 samples.

How the data were processed

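Ribosome-bound RNA was measured in 6 libraries from young adult *C. elegans* grown at 20 °C, 3 after 6 h with EtOH and 3 after 6 h with 4.5 µM antimycin A. Per the labels' protocols, RPL-22::3xHA expressed from the *tbh-1* promoter was immunoprecipitated with an anti-HA antibody, RNA was purified with the Absolutely RNA Nanoprep kit and libraries were made with the SureSelect XT HS2 mRNA kit. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.36, HISAT2, StringTie 2.1.4 and DESeq2 1.28.1 were used with genome build WBcel235; the HISAT2 version, the DESeq2 formula and the strand setting are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart from each other.

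The authors deposited TPM values for 46904 genes in 1 table of all libraries and 3 tables of the same-numbered pairs, whose TPM are identical to those of the first. The authors' tables also hold a ratio of TPM, a log2 ratio, a p-value and a q-value; the log2 ratio of the first pair's table is EtOH over antimycin A and the others are antimycin A over EtOH. The authors' q-value is below 0.05 for 2896 genes over all libraries and for 138, 30 and 26 genes in the tables of pairs 1, 2 and 3, as the authors' deposited tables give them. Genes without signal are listed at 1e-04 TPM in the files and were set to 0. One of 98 ribosomal protein and proteasome genes, *rpl-42*, is at 0 in some library, so a 0 can be a failed estimate and is written as listed at 0. TPM are shares of each library and hold no read counts, so depth is unknown; 30522 to 32608 of the genes were at 0 in a library. Columns of other samples numbered 0.

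The count test planned for count tables could not be used, since the values are TPM. The planned fallback was used in its place: limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(TPM + 1), pseudocount 1, group as the only term, for the 11099 genes at 1 TPM or more in at least 3 libraries (10834 protein-coding, 265 other). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and adjusted p values are Benjamini-Hochberg values from limma over all tested genes. Means, SDs and tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

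The design text states that the experiments were done independently, each with a control and a trained sample. Deviations from the group means correlated at 0.68, 0.31 and 0.59 for replicates 1, 2 and 3, and each library correlated best with the library of its own number, so the numbers were taken to pair the samples. The planned main fit has group as its only term and leaves this pairing out. The fit with the replicate number as a block is an alternative, and its value stands beside a result where it changes a call or moves a count by over 1.5 times. That fit leaves few residual degrees of freedom per gene, so limma takes much of each gene's variance from the other genes. A blocked p value can therefore be small where a gene's own pairs disagree.

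Before the data were examined, 31 gene lists were fixed, 20 of responses and 11 of cell type markers, and 29 had at least 3 tested members. The lists of other neuron transmitter classes and of coelomocytes had 2 tested members each and were not tested; *bas-1*, *unc-25*, *cup-5* and *rme-8* had adjusted p values of 0.390, 0.619, 0.356 (blocked 0.0419) and 0.994. Lists were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 29 lists. Symbols absent from the tables were matched to a synonym or left out. Genes named in the text follow a rule fixed beforehand: the 12 with the largest change in each direction among those that passed with 1 direction in all pairs, the 4 smallest p values of each response list and 3 of each marker list, and *tbh-1*, *tdc-1*, *cat-1*, *rpl-22*, *gcy-8*, *atg-9*, *crh-1*, *hsp-6* and *hsp-60*. *gcy-8*, whose promoter is on the transgene array, was below the filter (0.406, 0.379 and 0.507 TPM in EtOH and 1.00, 1.54 and 0.822 TPM in antimycin A). Genes named outside that rule are *inx-8*, *rrn-3.1* and *rpl-42* and, in the closing section, 7 family members; they were chosen after their values were seen.

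The same code was tested on simulated data for the comparison of antimycin A with EtOH over 11099 genes, with 50 planted genes per size. It recovered 0 of 50 at a log2 change of 0.5, 9 at 1, 46 at 2 and 50 at 4, and 2.78% of its calls were false. The simulated noise was independent between genes and libraries, without the deviations that the real same-numbered libraries share. Neither the recovery nor the false share can therefore be carried over to the real data. Alternatives were other scalings, pseudocounts and filters, sample quality weights, the replicate block, gene families left out, and each library or pair left out in turn. The planned DESeq2 test, voom and library size alone were not run, because they need counts or change nothing in TPM; the planned count-based scaling and voom weights were replaced by median-of-ratios scaling of TPM and limma with sample quality weights.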

Results

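The data are 6 libraries of ribosome-bound RNA from young adult *Caenorhabditis elegans*. Of these, 3 came from animals kept for 6 h on a bacterial lawn with ethanol (EtOH, the vehicle). The other 3 came from animals kept for 6 h on a lawn with 4.5 µM antimycin A, an inhibitor of respiratory complex III. The animals carried a transgene in which the promoter of *tbh-1*, the gene for tyramine beta-hydroxylase, drives the ribosomal protein RPL-22 with 3 copies of the HA epitope. Ribosomes were pulled down with an anti-HA antibody and the RNA bound to them was sequenced (translating ribosome affinity purification). The values stand for RNA on tagged ribosomes together with any RNA carried through the pull-down. Each of 3 independent experiments gave 1 EtOH and 1 antimycin A library. The series title places the comparison in a study of autophagy at synapses and aversive learning under stress, and the comparison asks how antimycin A changed the RNA bound to the tagged ribosomes. Values are TPM (each gene's share of a library's transcripts, scaled for length), which keep no sequencing depth, so the depth per library is unknown and no counting interval is given. The number of genes at 1 TPM or more was 11046, 10267 and 9951 in EtOH replicates 1 to 3 and 11608, 11242 and 10573 in antimycin A replicates 1 to 3.

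The most abundant RNA in 5 of the 6 libraries was *perm-2*, an eggshell permeability gene, at 66560 to 100797 TPM. In antimycin A replicate 3 the ribosomal RNA gene *rrn-3.1* was higher, at 102709 TPM. Ribosomal RNA took 12.5% ± 2.22 of the EtOH libraries and 13.9% ± 8.42 of the antimycin A libraries (SD, n = 3 each), with 23.5% in antimycin A replicate 3. The gene behind the promoter, *tbh-1* (WBGene00006541, WBcel235 chromosome X, 15500259 to 15504895), stood at 1666 TPM ± 66.8 in EtOH and 2098 TPM ± 616 in antimycin A (log2 fold change 0.29 ± 0.24 SE, adjusted p = 0.502). *rpl-22*, whose reads can come from the transgene as well as the endogenous gene, stood at 3229 TPM ± 1053 and 3621 TPM ± 1324 (0.14 ± 0.32, adjusted p = 0.854, and -0.11 after median-of-ratios scaling). Markers of several tissues were present. The tested intestine markers had a median of 542 TPM in EtOH and 257 TPM in antimycin A. The tested pan-neuronal markers had medians of 10.7 and 21.3 TPM. The gonadal sheath innexin *inx-8* read 2344 to 5465 TPM over the 6 libraries, and *snb-1*, the pan-neuronal marker with the highest mean over the libraries, read 88.3 to 457 TPM. Libraries correlated at a Spearman rho of 0.920 to 0.972 within a group and 0.818 to 0.886 between groups, across 11099 genes, which are not independent replicates. The first principal component held 61.2% of the variance and separated the groups, and the second held 27.8% and followed the replicate number.

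A large part of the RNA in the pull-down, which can include RNA carried through, differed between antimycin A and EtOH. Genes that rose included *cyp-33C5*, for a cytochrome P450, *gst-33*, for a glutathione S-transferase, and *hsp-16.2*, for a small heat shock protein. The vitellogenin gene *vit-4* fell, and 74 of 79 ribosomal protein genes fell (camera adjusted p = 8.81e-51; adjusted p = 0.533 with an estimated correlation). Of 11099 genes tested, 1579 were higher and 718 lower in antimycin A at an adjusted p below 0.05. Of these 2297 genes, 1962 changed at least 2-fold on the log2(TPM + 1) scale, 1389 higher and 573 lower. All 2297 moved in the same direction in each of the 3 same-numbered pairs. With the replicate number as a block, 3282 genes were higher and 1442 lower, among them all 2297. Both results use the same 6 libraries as the calls, so neither is an independent check of them. The median log2 fold change of all tested genes was 0.21. After median-of-ratios scaling, which removes that shift, 1474 genes were higher and 1145 lower (56.3% higher against 68.7%), and after quantile normalization 1423 and 1398 (50.4%). Without EtOH replicate 2 the counts were 991 and 410, and without EtOH replicate 3 they were 1082 and 494. They were 943 and 705 without antimycin A replicate 1 and 768 and 454 without antimycin A replicate 2. Genes below 1 TPM in all EtOH libraries cannot pass the filter once an antimycin A library is left out. This can lower the counts of genes higher in such fits, here and in the lists below. The authors' deposited table calls 2896 genes at q below 0.05, 1517 higher and 1379 lower. Of the 2297 genes called here, 1934 are called in the authors' deposited table in the same direction and 0 in the opposite one.

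**Figure D1:**
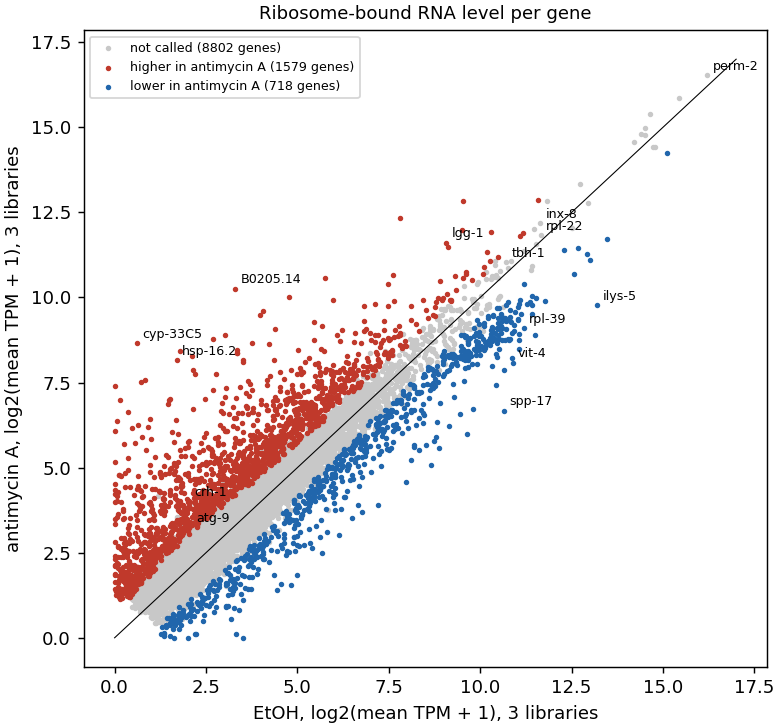
Mean TPM of each of the 11099 tested genes in the 3 EtOH libraries (x axis, log2 of mean TPM + 1) and the 3 antimycin A libraries (y axis, same scale); each point is 1 gene and the line marks equal values. The 1579 genes called higher are red and the 718 called lower are blue, while *tbh-1*, *rpl-22* and *perm-2* are among those not called (grey).

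The gene with the highest fitted fold change was *cyp-33C5*, a cytochrome P450 (WBGene00018261, chromosome V, 2245015 to 2247015). It rose from 0.518 TPM ± 0.375 to 401 TPM ± 43.5 (SD, n = 3 each; log2 fold change 8.08 ± 0.28 SE, adjusted p = 3.34e-07). *B0205.14* (WBGene00044646, chromosome I, 10726903 to 10727364) rose from 8.82 TPM ± 1.49 to 1224 TPM ± 279 (6.95 ± 0.24, adjusted p = 3.34e-07). The glutathione S-transferase *gst-33* rose from 2.47 TPM ± 0.383 to 341 TPM ± 73.1, and the omega-class *gsto-2* from 0.281 TPM ± 0.145 to 98.3 TPM ± 3.61. The other genes among the 12 with the highest values were *cyp-13A8*, *cyp-33C4*, the glucuronosyltransferases *ugt-9* and *ugt-61*, *oac-14*, *nspe-6*, *hsp-16.2* and *F48G7.12*. *F48G7.12* was listed at 0 in all 3 EtOH libraries and read 173, 170 and 164 TPM in antimycin A replicates 1 to 3. In the other direction *spp-17*, a saposin-like gene (WBGene00005002, chromosome I, 1016403 to 1017180), fell from 1616 TPM ± 391 to 101 TPM ± 10.9 (-3.97 ± 0.22, adjusted p = 2.16e-06). The invertebrate-type lysozyme gene *ilys-5* (WBGene00017691, chromosome X, 6533493 to 6536840) fell from 9352 TPM ± 1267 to 876 TPM ± 237 (-3.44 ± 0.24, adjusted p = 1.09e-05). The fatty acid elongases *elo-5* and *elo-6* fell from 469 TPM ± 104.1 to 46.6 TPM ± 10.2 and from 889 TPM ± 158 to 104.3 TPM ± 50.7. The remaining genes of the 12 lowest were *dct-18*, *gcsh-1*, *B0035.13*, *F46F2.3*, *K03H6.2*, *F13B6.2*, *Y39A3B.3* and the pseudogene *C49F5.9*. *Y39A3B.3* read 7.67, 11.2 and 12.2 TPM in EtOH and was listed at 0 in all 3 antimycin A libraries. *C49F5.9* was listed at 0, 0 and 23.1 TPM in antimycin A replicates 1 to 3, and its call (adjusted p = 0.0139) was lost without EtOH replicate 2 or antimycin A replicate 2 (highest adjusted p over the left-out libraries and pairs 0.173).

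The gene lists were tested with camera at a preset correlation, and 12 of the 29 that could be tested passed an adjusted p of 0.05, 7 shifted up and 5 down relative to all other genes. With an estimated correlation 0 of the 29 passed. The 3 other splits of the 6 libraries into 3 and 3 that part all 3 same-numbered pairs, as the real one does, gave 9 to 11 lists past the threshold, and the 6 that part 1 pair gave 10 to 13. The counts of single genes are given first for each list. The rotation test fry, which asks whether a list's genes move one way on balance, passed 7 lists.

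Detoxification genes rose in part. Of 32 tested genes of xenobiotic and glutathione metabolism, 18 rose, 2 fell and 12 were not called. Adjusted over the list alone, 21 rose and 2 fell. *ugt-61* (WBGene00018206, chromosome V, 4742427 to 4745373) rose from 5.41 TPM ± 0.551 to 434 TPM ± 75.6. *cyp-14A4* rose from 0.201 TPM ± 0.164 to 51.2 TPM ± 3.42 (5.45 ± 0.31) and *ugt-1* from 0.946 TPM ± 0.314 to 85.8 TPM ± 23.2 (5.45 ± 0.32). *gst-14* was listed at 0 in the 3 EtOH libraries and read 73.8, 80.2 and 46.4 TPM in antimycin A replicates 1 to 3. The list median was 1.21 (camera adjusted p = 1.80e-07, fry adjusted p = 3.61e-04; adjusted p = 0.333 with an estimated correlation). Without antimycin A replicate 1 or 2, 24 of the genes passed the filter on low values and 8 of them rose. Without antimycin A replicate 3, 24 passed and 12 rose. The filter needs 1 TPM in 3 libraries, so genes below that in all EtOH libraries drop out when 2 antimycin A libraries remain. Without EtOH replicate 1, 2 or 3 all 32 stayed, and 19, 15 and 17 rose.

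Heat shock genes rose in part. Of 21 tested members of the cytosolic heat shock list, 13 rose, 0 fell and 8 were not called, and 15 rose when adjusted over the list alone. *hsp-16.2*, a small heat shock protein gene (WBGene00002016, chromosome V, 1804334 to 1804971), rose from 2.24 TPM ± 0.503 to 285 TPM ± 143 (6.36 ± 0.34, adjusted p = 1.97e-06). The near-identical copies *hsp-16.1* and *hsp-16.11* share reads, so their separate values are uncertain. They read 15.8 TPM ± 4.35 and 14.7 TPM ± 4.21 in EtOH and 770 TPM ± 274 and 717 TPM ± 253 in antimycin A. *hsp-16.49*, also one of a pair of copies, read 9.24 TPM ± 2.27 and 331 TPM ± 78.0. The list median was 1.69 (camera adjusted p = 1.34e-09, fry adjusted p = 3.61e-04; adjusted p = 0.219 with an estimated correlation).

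Autophagy genes, which the series title concerns, were raised in part. Of 34 tested, 15 rose, 0 fell and 19 were not called. Adjusted over the list alone 19 rose and 1 fell, and with the replicate block 24 rose and 1 fell. *lgg-1*, the GABARAP/Atg8 homologue (WBGene00002980, chromosome II, 6346960 to 6347719), rose from 538 TPM ± 138 to 3133 TPM ± 353 (2.57 ± 0.23, adjusted p = 4.16e-05). The receptor gene *sqst-1* rose from 10.1 TPM ± 3.09 to 79.0 TPM ± 16.9 (2.86 ± 0.29). *bec-1*, the Beclin homologue, rose from 11.95 TPM ± 2.97 to 60.6 TPM ± 8.40 (2.27 ± 0.27) and *allo-1* from 58.9 TPM ± 11.01 to 231 TPM ± 22.1 (1.97 ± 0.21). *atg-9*, the gene for the transmembrane autophagy protein of the title (WBGene00020706, chromosome V, 349374 to 359016), read 3.23 TPM ± 3.11 in EtOH and 8.45 TPM ± 4.95 in antimycin A. It did not pass (1.22 ± 0.60, adjusted p = 0.208), was higher in 3 of 3 pairs, and passed with the replicate block (adjusted p = 2.27e-04). The authors' deposited table gives *atg-9* a log2 ratio of 1.39 and q = 0.0319. The list median was 0.99 (camera adjusted p = 1.84e-05, fry adjusted p = 0.0654; adjusted p = 0.916 with an estimated correlation).

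Ribosomal protein genes fell nearly throughout. Of 79 tested cytosolic ribosomal protein genes, with the tagged *rpl-22* left out, 74 fell, 0 rose and 5 were not called, and 75 fell when adjusted over the list alone. *rpl-39* (WBGene00004453) fell from 2344 TPM ± 152 to 548 TPM ± 26.1 (-2.09 ± 0.17, adjusted p = 2.73e-05) and *rpl-41.2* from 2115 TPM ± 186 to 430.2 TPM ± 80.9 (-2.31 ± 0.20). The list took 9.62% ± 0.851 of all TPM in EtOH and 3.41% ± 0.964 in antimycin A (SD, n = 3 each). The list median was -1.47, and -1.72 after median-of-ratios scaling and -1.07 after quantile normalization. Its camera adjusted p was 8.81e-51 and its fry adjusted p 0.0133 (adjusted p = 0.533 with an estimated correlation).

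Proteasome subunit genes gave a smaller change in the other direction. Of 33 tested, 6 rose, 0 fell and 27 were not called, with 6 also when adjusted over the list alone. Among them were *rpn-10* (0.88 ± 0.21, adjusted p = 0.0153) and *rpn-12* (0.79 ± 0.19, adjusted p = 0.0156). The count was 26 with the replicate block, 1 after median-of-ratios scaling and 13 after rescaling to protein-coding genes. It was 11 without EtOH replicate 1, 1 without antimycin A replicate 1, and 0 without EtOH replicate 2, EtOH replicate 3 or antimycin A replicate 2. The camera adjusted p was 6.61e-04 and the fry adjusted p 0.0877 (adjusted p = 0.916 with an estimated correlation).

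Genes of the mitochondrion moved in different ways. Of 44 tested nuclear genes of the respiratory chain, 15 fell, 0 rose and 29 were not called, with 18 lower when adjusted over the list alone and 25 with the replicate block. The ATP synthase gene *atp-3* fell from 810 TPM ± 159 to 287 TPM ± 80.5 (-1.51 ± 0.24, adjusted p = 0.00158). *atp-2* fell from 1042 TPM ± 130 to 380.4 TPM ± 127 (-1.50 ± 0.26, adjusted p = 0.00238), and *asg-2* and *atp-1* fell by 1.23 and 1.42 on the log2 scale. The list median was -0.45 (camera adjusted p = 1.34e-09, fry adjusted p = 0.126; adjusted p = 0.781 with an estimated correlation). Of 12 mitochondrially encoded genes limma called 0, with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. With the replicate block 2 were lower. These were *ctb-1* (267.5 TPM ± 219 and 172 TPM ± 136; adjusted p = 0.657, blocked 0.00120) and *ctc-3* (388 TPM ± 260 and 269 TPM ± 194; adjusted p = 0.695, blocked 0.00220). The list's median was 0.06 and its mean -0.06 (camera adjusted p = 0.412, fry adjusted p = 0.974; adjusted p = 0.922 with an estimated correlation), and the median was -0.19 after median-of-ratios scaling and -0.22 after quantile normalization. Leaving out 1 library breaks a same-numbered pair, and the median then moved widely. It was 0.62 without EtOH replicate 1 and 0.12 without EtOH replicate 2, and -0.89 without EtOH replicate 3, where camera passed (adjusted p = 0.00954). It was -0.78 without antimycin A replicate 1, -0.11 without antimycin A replicate 2 and 0.76 without antimycin A replicate 3. With both libraries of replicate 1, 2 or 3 left out, which keeps the other pairs whole, the median was 0.03, 0.06 and -0.04.

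Of 17 tested genes of the mitochondrial stress response, 2 rose, 0 fell and 15 were not called, with 1 higher when adjusted over the list alone and 4 higher and 1 lower with the block. *atfs-1*, the transcription factor of the mitochondrial unfolded protein response, rose from 19.3 TPM ± 4.77 to 91.3 TPM ± 14.1 (2.201 ± 0.25, adjusted p = 1.97e-04). The protease gene *ymel-1* passed at an adjusted p of 0.0477, and 1 gene of the list rose without EtOH replicate 2, EtOH replicate 3, antimycin A replicate 1 or antimycin A replicate 2. The mitochondrial chaperone genes commonly used as reporters of that response did not pass with group as the only term and passed with the replicate block. *hsp-6* stood at 38.5 TPM ± 22.5 and 61.3 TPM ± 35.5 (0.66 ± 0.46, adjusted p = 0.410, blocked 0.00129). *hsp-60* stood at 84.2 TPM ± 21.7 and 56.3 TPM ± 17.5 (-0.59 ± 0.30, adjusted p = 0.221, blocked 0.00254), and passed after median-of-ratios scaling (-0.83, adjusted p = 0.0194) and quantile normalization (-0.87, adjusted p = 0.0160) and with quality weights (adjusted p = 0.00223). The authors' deposited table gives q = 0.621 for *hsp-6* and q = 0.00108 for *hsp-60*. The median of the list was 0.19 (camera adjusted p = 0.754, fry adjusted p = 0.443) and turned to -0.04 after median-of-ratios scaling and -0.10 after quantile normalization.

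Redox and hypoxia genes gave 8 of 22 higher, 0 lower and 14 not called, with 8 when adjusted over the list alone and 13 with the block. They were led by *cysl-2* (12.4 TPM ± 3.26 to 154 TPM ± 29.9) and *nhr-57* (1.78 TPM ± 0.798 to 27.5 TPM ± 5.80), both known HIF-1 targets. The camera adjusted p was 0.0189 and the fry adjusted p 0.00616 (adjusted p = 0.781 with an estimated correlation), and camera did not pass without EtOH replicate 1 (adjusted p = 0.08245) or after median-of-ratios scaling (adjusted p = 0.05085). Of 18 glycolysis genes 6 rose, 0 fell and 12 were not called, with 6 when adjusted over the list alone and 9 higher and 1 lower with the block. *ldh-1*, for lactate dehydrogenase, rose from 48.8 TPM ± 4.02 to 176 TPM ± 18.5. The glycolysis list did not pass camera (adjusted p = 0.0551, fry adjusted p = 0.110; adjusted p = 0.922 with an estimated correlation) and passed with the replicate block (adjusted p = 0.0435; adjusted p = 0.734 with an estimated correlation). It passed in 13 of 23 settings, among them no filter on low values (adjusted p = 0.0101), a pseudocount of 5 (adjusted p = 0.0482), protein-coding rescaling (adjusted p = 0.03585) and quantile normalization (adjusted p = 0.0381). It also passed without EtOH replicate 1, EtOH replicate 3 or any 1 antimycin A library (adjusted p 0.0235 to 0.0496), and 3 of its genes rose without EtOH replicate 2.

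**Figure D2:**
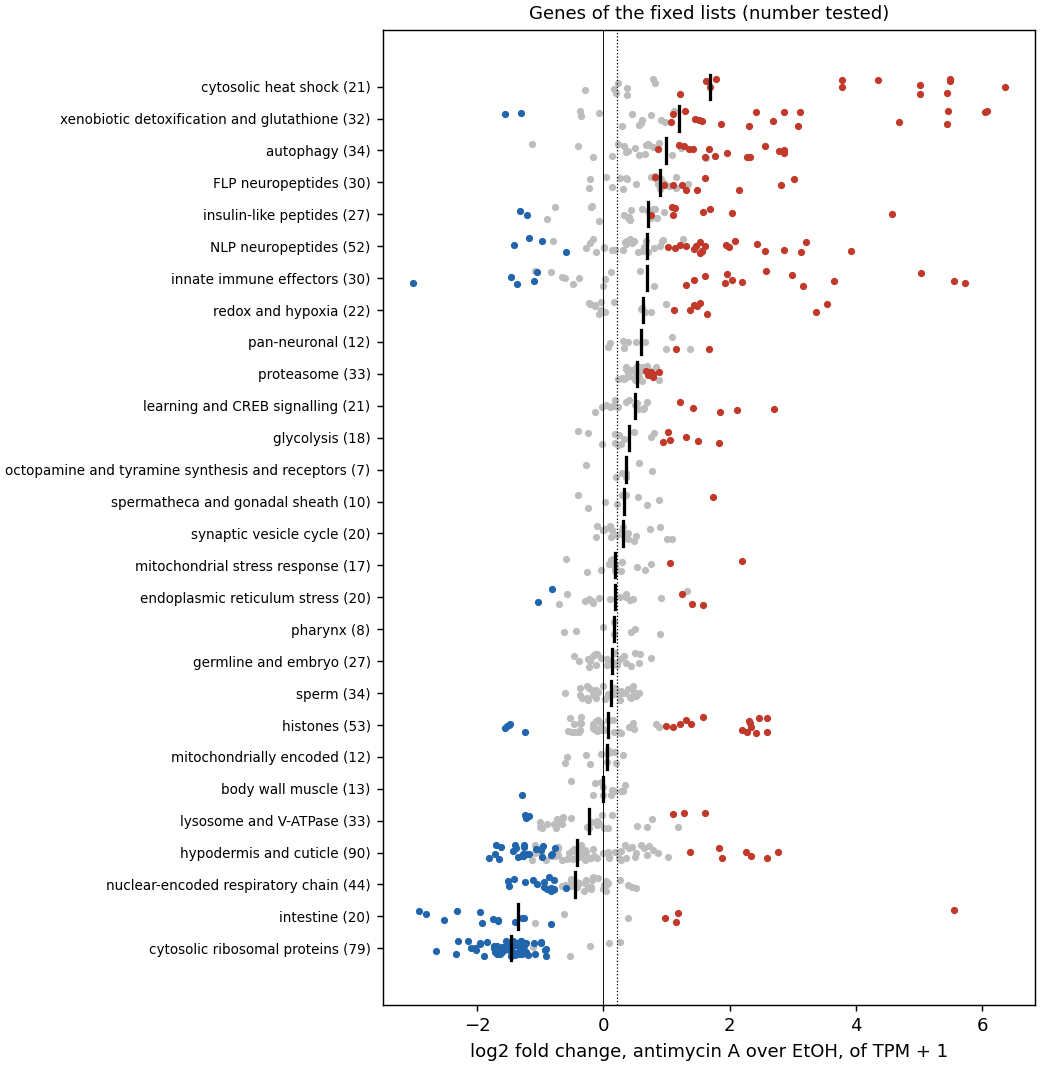
Log2 fold change, antimycin A over EtOH on the TPM + 1 scale (x axis), of each tested member of the fixed lists with at least 7 tested genes (y axis, number tested in brackets); red and blue points were called higher and lower, grey points were not called, bars are list medians and the dotted line is the median of all genes, 0.21. The ribosomal protein list sits lowest at a median of -1.47 and the heat shock list highest at 1.69.

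Neuropeptide genes were higher more often than lower. Of 30 tested FLP genes 10 rose, 0 fell and 20 were not called, with 15 higher when adjusted over the list alone and 20 with the block. *flp-16* rose from 38.8 TPM ± 18.1 to 300.0 TPM ± 20.6 (3.02 ± 0.31, adjusted p = 1.03e-04) and *flp-5* from 9.16 TPM ± 1.79 to 70.9 TPM ± 14.1 (2.82 ± 0.27, adjusted p = 6.71e-05). Without EtOH replicate 2 or antimycin A replicate 2, 5 FLP genes rose, and without EtOH replicate 3 or antimycin A replicate 1, 6 did. Of 52 tested NLP genes 20 rose, 4 fell and 28 were not called. Adjusted over the list alone 22 rose and 4 fell, and with the block 31 and 5. *nlp-48* rose from 11.5 TPM ± 3.52 to 187 TPM ± 41.1 and *nlp-14* from 11.4 TPM ± 2.42 to 107 TPM ± 18.05. Without antimycin A replicate 2, 12 NLP genes rose, and 2 fell without EtOH replicate 2, EtOH replicate 3, antimycin A replicate 1 or antimycin A replicate 2. The camera adjusted p was 5.71e-04 for FLP genes and 6.79e-04 for NLP genes (adjusted p = 0.916 and adjusted p = 0.829 with an estimated correlation). The fry adjusted p was 0.0654 for FLP genes and 0.0207 for NLP genes.

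Of 27 insulin-like peptide genes 8 rose, 2 fell and 17 were not called. Adjusted over the list alone 10 rose and 2 fell, and with the block 14 and 4. *ins-11* rose from 0.125 TPM ± 0.117 to 25.8 TPM ± 4.07 (4.57 ± 0.32; list camera adjusted p = 0.152, fry adjusted p = 0.00531; adjusted p = 0.879 with an estimated correlation). After median-of-ratios scaling 5 rose and 3 fell. Without EtOH replicate 2, 3 rose and 0 fell, and without EtOH replicate 3, 6 rose and 0 fell, and camera passed in both (adjusted p = 0.0382 and adjusted p = 0.03255). Without antimycin A replicates 1, 2 and 3 in turn, 4, 2 and 4 rose. The pan-neuronal markers gave 2 of 12 higher, *sbt-1* (91.8 TPM ± 1.18 to 206 TPM ± 14.1) and *ida-1*, 0 lower and 10 not called. The count was 3 when adjusted over the list alone, 6 with the block, 6 without EtOH replicate 1 and 1 without EtOH replicate 2 or antimycin A replicate 2 (list median 0.59, camera adjusted p = 0.0769, fry adjusted p = 0.126; adjusted p = 0.922 with an estimated correlation). Camera passed without EtOH replicate 1, antimycin A replicate 1 or antimycin A replicate 3 (adjusted p 0.0305 to 0.0496) and with no filter on low values (adjusted p = 0.0227).

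Learning and CREB pathway genes gave 5 higher, 0 lower and 16 not called of 21 tested, with 5 when adjusted over the list alone and 10 with the block (camera adjusted p = 0.137, fry adjusted p = 0.245; adjusted p = 0.922 with an estimated correlation). Camera passed without EtOH replicate 1 or antimycin A replicate 3 (adjusted p = 0.04375 and adjusted p = 0.0305). *tir-1*, the SARM homologue, rose from 2.60 TPM ± 0.333 to 22.6 TPM ± 3.80 (2.71 ± 0.30, adjusted p = 1.77e-04). *crh-1*, the CREB homologue (WBGene00000793, chromosome III, 11657738 to 11693837), rose from 3.08 TPM ± 2.43 to 15.2 TPM ± 3.01 (2.13 ± 0.42, adjusted p = 0.00565). *casy-1* rose from 59.2 TPM ± 15.3 to 138 TPM ± 30.2 and *hen-1* from 6.29 TPM ± 1.70 to 19.2 TPM ± 8.55. Both calls were lost without antimycin A replicate 2, where 2 genes of the list passed, and that of *hen-1* also without EtOH replicate 3, where 3 passed. Of 20 synaptic vesicle cycle genes limma called 0, with 3 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.772, fry adjusted p = 0.572). With the replicate block 4 passed, 4 passed without EtOH replicate 1, and 1 passed without antimycin A replicate 3. *snb-1*, the synaptobrevin gene, read 166 TPM ± 87.2 and 344 TPM ± 135 (1.09 ± 0.41, adjusted p = 0.0911, blocked 7.36e-07). Of 7 genes of octopamine and tyramine synthesis and reception limma called 0, with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.809, fry adjusted p = 0.553). With the block 1 passed, *ser-3* (adjusted p = 0.309, blocked 0.0247, and 0.0969 with the block after median-of-ratios scaling). It was higher in antimycin A in pairs 1 and 2 and lower in pair 3 (1.04 TPM and 0.909 TPM), and it passed without antimycin A replicate 3 (1.31, adjusted p = 0.0265). *tdc-1*, the tyrosine decarboxylase gene, read 13.5 TPM ± 8.72 and 16.3 TPM ± 5.48 (adjusted p = 0.666). *cat-1*, near the filter of 1 TPM, read 1.38 TPM ± 0.377 and 2.60 TPM ± 0.990 (adjusted p = 0.280, blocked 0.0718).

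**Figure D3:**
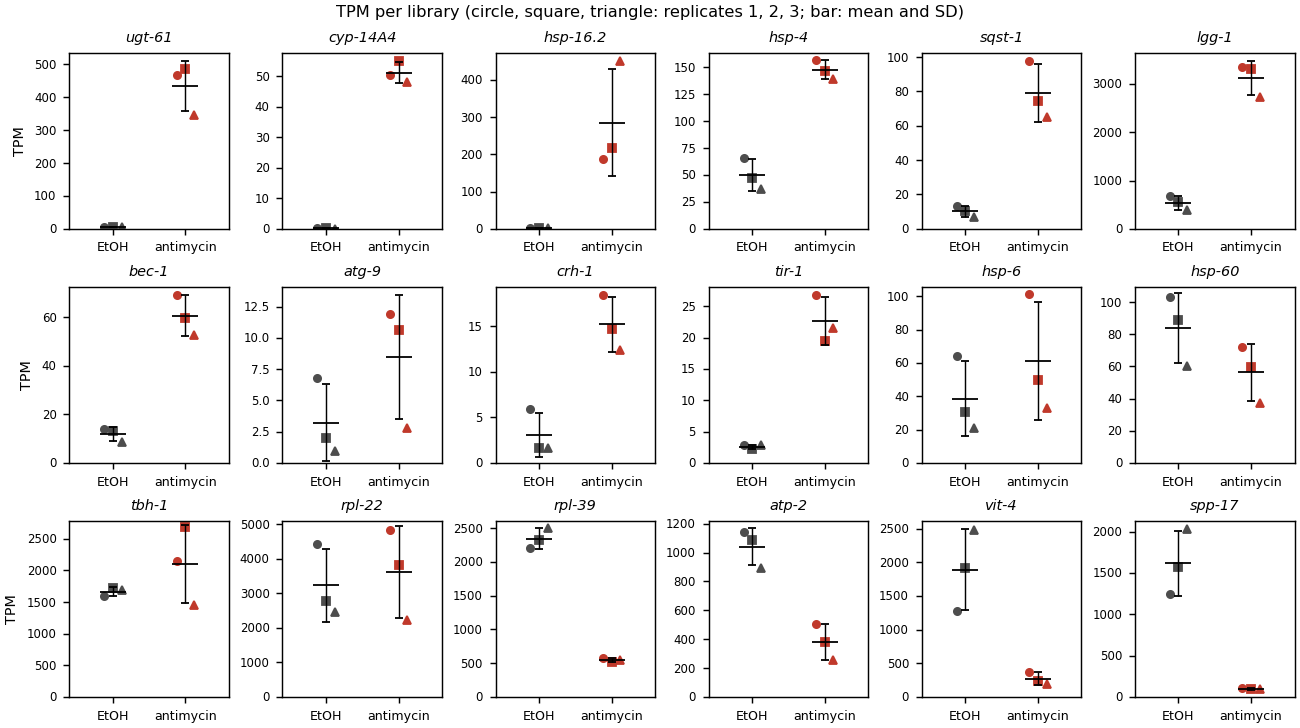
TPM (y axis, linear from 0) of 18 named genes in each library, EtOH in grey and antimycin A in red, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3. *lgg-1*, *sqst-1*, *bec-1*, *crh-1* and *tir-1* do not overlap between groups, *atg-9* and *hsp-6* do, and *vit-4* and *spp-17* lie lower in antimycin A.

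Stress and immune lists held genes that moved both ways. Of 30 innate immune effectors 14 rose, 5 fell and 11 were not called. Adjusted over the list alone 15 rose and 7 fell, and with the block 16 and 10. *cnc-4*, a caenacin gene, rose from 3.42 TPM ± 0.269 to 234 TPM ± 8.58 (5.73 ± 0.22). The lysozyme genes *ilys-2* and *ilys-3* rose from 5.78 TPM ± 1.86 to 216 TPM ± 32.04 and from 0.545 TPM ± 0.104 to 74.5 TPM ± 27.5. The immune list's camera adjusted p was 0.137 and its fry adjusted p 0.00531 (adjusted p = 0.916 with an estimated correlation), and 3 genes fell without EtOH replicate 2, EtOH replicate 3 or antimycin A replicate 3. Camera passed for it without EtOH replicate 2 or EtOH replicate 3 (adjusted p = 0.01725 and adjusted p = 0.00696), after quantile normalization (adjusted p = 0.01065) and with no filter on low values (adjusted p = 0.0367). In the endoplasmic reticulum stress list 3 of 20 rose, 2 fell and 15 were not called, with 4 and 2 when adjusted over the list alone and 6 and 4 with the block. The chaperone gene *hsp-4* rose from 49.9 TPM ± 14.5 to 148 TPM ± 8.86 and *xbp-1* from 87.9 TPM ± 24.6 to 232 TPM ± 54.1. The disulfide isomerase genes *pdi-3* and *pdi-6* fell by 1.04 and 0.82 on the log2 scale (list camera adjusted p = 0.813, fry adjusted p = 0.717). Its median of 0.18 turned to -0.05 after median-of-ratios scaling, -0.05 without EtOH replicate 3 and -0.01 without antimycin A replicate 1. Without antimycin A replicate 3, 5 genes of that list rose and 1 fell, and 0 fell without EtOH replicate 2. Without EtOH replicate 3 or antimycin A replicate 2, 1 fell.

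Of 33 lysosome and V-ATPase genes 3 rose, 3 fell and 27 were not called, with 4 and 5 when adjusted over the list alone and 7 and 15 with the block. *scav-3* rose from 40.8 TPM ± 6.25 to 101 TPM ± 22.3, as did *ncr-1*, and *asp-4* fell from 253 TPM ± 28.4 to 115 TPM ± 35.6, as did *vha-20*. After median-of-ratios scaling 4 rose and 15 fell. Without antimycin A replicate 1, 8 fell, and without EtOH replicate 2, 0 fell. Without EtOH replicate 1 or antimycin A replicate 3, 5 rose. Its median of -0.22 was 0.035 with sample quality weights. The camera adjusted p was 0.00497 and the fry adjusted p 0.722 (adjusted p = 0.922 with an estimated correlation; adjusted p = 0.0576 after quantile normalization). Of 53 histone genes, which are near-identical copies and therefore uncertain, 15 were called higher and 5 lower, with the same counts when adjusted over the list alone. *his-44* read 3.70 TPM ± 0.0670 and 24.4 TPM ± 3.72. The histone median was 0.08 and turned to -0.10 after median-of-ratios scaling, -0.01 without EtOH replicate 2, -0.15 without EtOH replicate 3 and -0.04 without antimycin A replicate 1 (camera adjusted p = 0.809, fry adjusted p = 0.101).

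Markers of other tissues moved with treatment in the intestine and cuticle lists. Of 20 intestine markers 13 fell, 4 rose and 3 were not called, with 14 and 4 when adjusted over the list alone. The vitellogenin gene *vit-4* fell from 1889 TPM ± 604 to 270.1 TPM ± 93.9 (-2.80 ± 0.30, adjusted p = 1.31e-04) and *vit-3* from 2147 TPM ± 831 to 358 TPM ± 88.4. The ferritin gene *ftn-1* rose from 3.56 TPM ± 1.19 to 215 TPM ± 66.7 (5.55 ± 0.30, adjusted p = 1.97e-06). The list took 2.00% ± 0.116 of all TPM in EtOH and 0.783% ± 0.269 in antimycin A. Its median was -1.35 (camera adjusted p = 8.41e-07, fry adjusted p = 0.0877; adjusted p = 0.781 with an estimated correlation), and 2 markers rose without EtOH replicate 3, antimycin A replicate 1 or antimycin A replicate 2.

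Of 90 cuticle and hypodermis genes 24 fell, 7 rose and 59 were not called, with 31 and 8 when adjusted over the list alone and 38 and 13 with the block. Those that rose included *dpy-3* (0.0626 TPM ± 0.108 to 5.47 TPM ± 1.41) and *dpy-10* (0.233 TPM ± 0.0658 to 5.00 TPM ± 1.51). The list median was -0.42. It was 1.87 once the genes with a col symbol were left out, together with the sperm and histone families, and TPM were rescaled. This left 8 genes of the list, *dpy-3* and *dpy-10* among them. Without EtOH replicate 2, 12 fell, and without antimycin A replicate 2, 14 fell and 3 rose. Without antimycin A replicate 1, 2 rose, and without antimycin A replicate 3, 3 rose. The camera adjusted p was 4.67e-07 and the fry adjusted p 0.267 (adjusted p = 0.781 with an estimated correlation).

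The other marker lists gave few calls. Of 13 body wall muscle genes 1 fell, *mlc-2* (1642 TPM ± 325 to 674 TPM ± 170; list camera adjusted p = 0.242, fry adjusted p = 0.865), with 2 lower with the block, where *pat-10* also passed (adjusted p = 0.176, blocked 0.0197). Of 10 sheath and spermatheca genes 1 rose, *fln-1* (adjusted p = 0.0290; list camera adjusted p = 0.679, fry adjusted p = 0.443), with 0 when adjusted over the list alone and 4 with the block. The *fln-1* call was lost without EtOH replicate 2, EtOH replicate 3, antimycin A replicate 1 or antimycin A replicate 2. In limma 0 of 27 germline, 0 of 34 sperm, 0 of 8 pharynx and 0 of 3 glia genes passed, and at an unadjusted p under 0.05 the counts were 1, 0, 1 and 1. With the block 4 germline genes were higher and 1 lower, 1 sperm gene was lower, and 1 pharynx and 1 glia gene were higher. Without EtOH replicate 1, limma called 3 germline genes, 1 sperm gene and 1 glia gene higher. Their camera adjusted p values were 0.610 for germline, 0.494 for sperm and 0.813 for both pharynx and glia, and fry passed for 0 of these 4 lists (adjusted p 0.406 to 0.865; adjusted p = 0.922 for all 4 with an estimated correlation). The sperm list passed camera without EtOH replicate 2 or antimycin A replicate 3 (adjusted p = 0.0496 and adjusted p = 0.00739), with its median of 0.13 turned to -0.22 and -0.10.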

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

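The tests with protein-coding rescaling, rescaling without ribosomal protein genes, quantile normalization, and the block combined with gene length or with scaling were chosen after seeing the data. All 2297 calls kept their direction without any 1 library in which they could be tested; 1029 lost significance without some 1 library, 283 fell below the filter without some 1 library, and 1084 did neither. Of 98 called named genes, 15 lost the call without some 1 library and 0 changed sign. Named genes that fell below the filter in such a fit, *cyp-33C5* and *F48G7.12* among them, could not lose the call there. They are not among the 15 for that reason. Without any 1 library or pair, genes higher ranged from 391 to 2059, genes lower from 162 to 705, genes changed at least 2-fold from 553 to 2389 and lists from 13 to 16. The lowest counts came without the replicate 2 pair (391, 162 and 553), and 964, 372 and 1268 without the replicate 3 pair. Without antimycin A replicate 2, 1184 genes changed at least 2-fold. The replicate block gave 3282 higher and 1442 lower, with gene-length correction 3274 and 1391, and with median-of-ratios scaling 2415 and 2144; beyond the results where its value is given, and 21 named genes it added in all, the block lost 0 of the called named genes. Genes lower numbered 1145 after median-of-ratios scaling and 1398 after quantile normalization. Sample quality weights gave 5698 and 1798, but the weights did not converge and put 6.42 and 8.04 on the replicate 2 libraries against 0.213 to 0.794 on the others, so those counts rest on 1 pair. Lists past the threshold numbered 0 with an estimated correlation; 10 of the 12 passed in all 23 settings with the preset one, the lysosome list in 22 and the redox list in 21. Without 1 pair camera also passed for the glycolysis list (any pair, adjusted p 0.0226 to 0.0454), the pan-neuronal list (pair 1 or 3, 0.0282 and 0.0422), and the learning (pair 1, 0.0333), insulin (pair 2, 0.0345) and immune (pair 3, 0.0386) lists. Genes reversed as follows, none past the threshold in either setting: *rme-8* (-0.052 after rescaling without ribosomal protein genes, -0.14 after median-of-ratios scaling with and without the block, -0.28 after quantile normalization, -0.044 with the block and gene length), *rpl-22* (-0.11 after median-of-ratios scaling with and without the block), *ndfl-4* (-0.23 with quality weights, -0.13 after quantile normalization), *unc-25* (-0.11 and -0.018 likewise), *nduo-6* (-0.062) and *perm-2* (-0.27) after quantile normalization. The cuticle list passed camera in both directions (1.87 without the col, sperm and histone families, which its construction causes). List medians that changed sign were, after median-of-ratios scaling, mitochondrial stress (-0.04), mitochondrially encoded (-0.19), endoplasmic reticulum stress (-0.05), histones (-0.10), germline (-0.10), sperm (-0.06) and pharynx (-0.07), and all of these except endoplasmic reticulum stress also after quantile normalization. With quality weights the lysosome (0.035) and body wall muscle (0.15) medians turned positive, body wall muscle also after protein-coding rescaling (0.021), and medians of histones (pseudocount 5) and sperm (TPM above 5) fell just below 0. Without 1 library the germline median fell to -0.195 (antimycin A replicate 1), that of glia to -0.41 (antimycin A replicate 1), and that of body wall muscle rose to 0.26 (EtOH replicate 1). Without 1 library or pair, *rme-8* ranged from -0.22 to 0.21, *rpl-22* ranged from -0.105 to 0.46, *nduo-6* ranged from -0.47 to 1.01, *ctb-1* ranged from -1.269 to 0.040 and *ctc-3* ranged from -1.31 to 0.20. The causes of the others were not tested. Depth is unknown, and the simulated genes changed by 0.5 on the log2 scale were missed.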

Other observations

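The tests of gene families, *rpl-22* against other ribosomal protein genes, the unadjusted counts of other splits, the split under scaling and gene-length correction, intestine and sheath RNA, the share of ribosomal protein genes, and the quantile setting were chosen only after the results were seen; the protein-coding rescaling was chosen after the ribosomal RNA shares were seen, with its bounds set before its result. Beyond the fixed lists, cytochrome P450 and nuclear hormone receptor genes, grouped by symbol, were higher far more often than lower. Of 47 cyp genes 28 rose and 0 fell, for example *cyp-33C8* from 9.27 TPM ± 1.097 to 349 TPM ± 31.7 (5.09 ± 0.21, adjusted p = 5.06e-07); under median-of-ratios scaling 26 rose and 1 fell, and with the replicate block 36 and 1. Of 145 nhr genes 51 rose and 0 fell, among them *nhr-58* (1.94 TPM ± 0.230 to 30.8 TPM ± 5.08) and *nhr-142* (1.38 TPM ± 0.416 to 27.6 TPM ± 4.63); with the replicate block 85 rose and 0 fell, and after quantile normalization 41 and 2. Mitochondrial ribosomal protein genes went the way of the cytosolic ones: 16 of 42 mrpl genes and 9 of 29 mrps genes fell and 0 rose, among them *mrpl-36* (114 TPM ± 0.924 to 39.6 TPM ± 7.43), *mrpl-14*, *mrps-28* and *mrps-18.C*, with 26 and 17 lower with the replicate block, 24 and 15 after median-of-ratios scaling and 29 and 19 after quantile normalization. Over the 88 families with at least 10 tested genes the camera adjusted p was 1.73e-11 for cyp, 3.52e-07 for nhr, 7.59e-11 for mrpl and 8.09e-08 for mrps, and each was lost (adjusted p = 0.999 for all 4 with an estimated correlation).

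*rpl-22*, the gene carried by the transgene, had a higher fold change than 78 of the 79 other ribosomal protein genes, at 0.14 against a list median of -1.47. Reads of the tagged copy and the endogenous gene are not separated in these tables, so its source was not tested.

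Gene calls and list calls behaved differently under other splits of the 6 libraries. The real split was the only 1 of 10 to call genes, with 1579 higher, 718 lower and 1962 changed at least 2-fold against a highest other count of 0 by limma; 10 splits are too few for a share under 0.05. At an unadjusted p below 0.05 the real split gave 3407 genes, and the split of EtOH replicate 1 with antimycin A replicates 1 and 2 from the rest gave 3234, with a smallest adjusted p of 0.0856, which points to a structure of the samples besides treatment; the other 8 gave 14 to 375. Those 3 libraries had the highest median-of-ratios factors (1.233, 1.392 and 1.093 against 0.759 to 0.8425), the most genes at 1 TPM or more (11046, 11608 and 11242 against 9951 to 10573) and positive correlations of deviation with gene length (0.287, 0.261 and 0.0545 against -0.155 to -0.270), across genes. That split gave 1479 genes at an unadjusted p below 0.05 after median-of-ratios scaling and 3023 after gene-length correction, against 3716 and 3481 for the real split. For lists the real split gave 12. The 3 others that part all 3 pairs gave at most 11, which is too few splits for a share under 0.05. The 6 that part 1 pair keep 2 pairs together and gave up to 13, and 4 of all 10 gave 12 or more. Gene length throughout is the genomic span of a gene, introns included. A trend on that span that differs between experiments was tested as a cause of the shared deviations of same-numbered libraries. Their mean correlation was 0.524 and stayed at 0.510 (0.5095) after each library's trend was removed, which argues against a trend on genomic span. A trend on transcript length was not tested.

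More genes were called higher (68.7%) than lower. A different share of ribosomal RNA is argued against, since the share higher was 70.35% after rescaling to protein-coding genes. The fall of ribosomal protein genes as the whole cause is argued against, since the share higher was 63.35% after rescaling to the total without them, and their fall from 9.62% to 3.41% raises all other shares by 0.0959 on the log2 scale against a median of 0.21. That TPM are shares of a total, so that all genes that fell from a large share raise the others, stays open. The share higher was 56.28% after median-of-ratios scaling, between the bounds of 55% and 60% set beforehand. It was 52.97% with that scaling and the replicate block, under the 55% bound, in a setting chosen after seeing the data. It was 50.4% after quantile normalization, which forces equal distributions. Unscaled, it was 57.22% without antimycin A replicate 1 and 74.93% without EtOH replicate 1. Without 1 pair it was 64.53% to 72.16%. A broad biological rise after antimycin A also stays open, untested.

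Of 20 intestine markers 13 fell in antimycin A although the tag is expressed from the *tbh-1* promoter. A smaller share of intestinal RNA as the whole cause is argued against: the SD of the 20 markers' log2 fold changes was 6.648 times their median standard error, and 4 of them rose. A smaller share together with genes induced in the intestine cannot be told apart from lower expression. The ratio was 2.82 over the 16 markers that did not rise. Those markers were picked by the change under test, and markers also expressed elsewhere would shift less, so this ratio cannot decide. The bound first set for that test, a ratio over 2, would argue against a smaller share together with induced genes. It was replaced after the 2.82 was seen. A response of the intestine itself to antimycin A stays open, untested.

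*inx-8* was among the most abundant genes, and 1 hypothesis is that most of the RNA comes from the gonadal sheath, where *tbh-1* is also expressed, and not from neurons. *inx-8* (2344 to 5465 TPM) and *inx-9* (415 to 1051 TPM) both lay above every pan-neuronal marker in 6 of 6 libraries. The median of the sheath and spermatheca list lay above that of the pan-neuronal list in 2 of 6 libraries. That median cannot settle the source, because the list mixes sheath with spermatheca genes. Its members other than *inx-8* and *inx-9* had means of 0.429 to 37.3 TPM over the libraries. Over the 6 libraries *tbh-1* read 1455 to 2683 TPM, *tdc-1* 8.33 to 23.6 TPM and *cat-1* 1.01 to 3.57 TPM. The levels of *inx-8* and *inx-9* go with a sheath contribution, but *inx-8* was picked for its abundance. How much RNA came from each source cannot be told, because both lists hold genes near the floor and no input RNA was analysed here. Changes in the gene lists above therefore cannot be assigned to neurons or to the sheath.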
